A study of Mus musculus with 6 samples.

How the data were processed

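Poly(A) RNA of 6 samples of the mouse renal tubular epithelial line TCMK1 was sequenced in paired ends on an Illumina instrument, per the labels' protocols. All samples received Ang II, and the labels put 3 in a control group and 3 in a YOD1 overexpression group. How YOD1 was introduced, and whether the controls carried an empty vector, is not given in the sources used here. The library strand is not stated either, so reads of overlapping and antisense genes cannot be assigned with certainty.

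The authors deposited 1 table with an FPKM value per gene and library, fragments scaled to transcript length and to mapped fragments of the library, per the file headers. The submitters' processing notes name HISAT2 2.0, StringTie 1.3.0, Bowtie 0.12.2 and the build mm8, with no role or order. The same table holds the authors' fold ratio of group means, its log2 value, and a p-value and q-value per gene, per the file headers. The deposited fold ratio equalled the ratio of the mean FPKM of both groups, with a largest relative difference of 3.4e-13, and the authors' mark of significance followed q under 0.05 with an absolute log2 fold change of at least 1 in all genes, with 0 departures. The test behind the authors' p-values is not given in the sources used here. The number of columns of per-sample values left unused was 0.

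The design fixed before the data were examined named a count-based test, with limma on log2(FPKM + 1) in its place for a table without counts. The table holds FPKM only, so limma was used and the count-based alternatives (other size factors, library-size scaling alone, other count tests, voom and the comparison of counts with FPKM) were not run. Read depth is unknown from FPKM. The relative depth of the libraries was estimated from the commonest ratio of values under 0.1 FPKM between libraries, which 5.51% to 7.17% of the low genes shared, so this estimate is rough. Library pairs were compared, and each pair had 0 to 6 genes with identical values above 0, so none was treated as a copy.

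Values were transformed to log2(FPKM + 1), and genes with at least 1 FPKM in at least 3 of 6 libraries were kept, which left 11483 of 28789. Groups were compared with limma 3.58.1 in R 4.3.3 (linear model per gene, moderated variances with an intensity trend, two-sided, Benjamini-Hochberg adjustment) at an adjusted p of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. An exact permutation of 3 against 3 libraries cannot give a p below 0.1, so none is reported. Tests on simulated data for this comparison, with 11483 genes and 200 changed ones, recovered 93% of changes of 1 and 100% of changes of 2 on the log2 scale. They gave 16 false calls among 209 and 0 calls among the unchanged gene lists. Each simulated change was equal in all YOD1 libraries, without trends shared across genes. The recovered shares therefore do not give the power of the test in the data. The simulated noise was independent between genes, and the unchanged lists were drawn at random. The 0 therefore says nothing about lists whose members vary together, as in the data (estimated correlation 0.75 for interferon-stimulated genes).

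Gene lists, 33 in all, were fixed before the data were examined and tested with camera from limma (preset correlation 0.01, at least 5 tested members, 31 lists), with an estimated correlation and with fry as alternatives. Fry asks whether the genes of a list move in 1 direction on balance and does not compare them with other genes. Terms of GO and KEGG from the deposited table, with 10 to 500 tested genes, were tested by Fisher's exact test, one-sided, separately for higher and lower calls. Named genes followed a rule fixed in advance: Yod1 and Jak2, the 10 calls of largest change per direction with non-overlapping groups and a mean of at least 1 FPKM (the 10 of lowest p where fewer passed, said to be past or not past the threshold), up to 4 called members per list, and 12 genes chosen for the tissue and treatment. Other members of the lists were named as examples after their values were seen, and the values of some members are not reported here.

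The alternatives set in advance were no filter, a filter at 5 FPKM, an added absolute log2 fold change of at least 1, a pseudocount of 0.1, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were median-ratio scaling, a correction of each library for transcript length and GC content by splines with 4 degrees of freedom, and FPKM rescaled to a common total after rRNA genes were left out. Lengths and GC came from the longest annotated transcript of each gene in GENCODE M21, which matched 99.2% of tested genes by transcript identifier. That annotation belongs to another build than mm8, so no coordinates are given. Numbers were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.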

Results

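RNA was sequenced from TCMK1 cells, a mouse renal tubular epithelial cell line, all treated with angiotensin II (Ang II). There were 3 control libraries and 3 libraries from cells that overexpressed YOD1, a deubiquitinase of the OTU family. The deposited table listed 28789 genes in FPKM. Between 22045 and 23374 genes per library had a value above 0, and the FPKM of a library summed to between 314172 and 352209. The read depth is unknown from FPKM alone, but the steps between low values put the YOD1 libraries at 0.804 to 0.843 of the depth of control 1, and the other controls at 0.977 and 1.02. Log2 values of library pairs correlated across genes with r from 0.971 to 0.989 within a group and from 0.955 to 0.981 between groups. The first principal component held 47.4% of the variance, and YOD1 library 3 had the most extreme score on it (-36.4). The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

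The series describes its purpose as finding pathways that YOD1 regulates in Ang II-treated TCMK1 cells, and its title names JAK2, a tyrosine kinase that activates STAT transcription factors, as a protein stabilised by YOD1. Yod1 (ENSMUSG00000046404) stood at 0.761 ± 0.079 FPKM in the controls (SD, n = 3) and at 3.72 ± 3.33 FPKM in the YOD1 libraries (SD, n = 3), a ratio of means of 4.88. All 3 YOD1 libraries lay above all 3 controls, with values of 1.73, 7.56 and 1.86 FPKM. The log2 fold change on the log2(FPKM + 1) scale was 1.21 with an SE of 0.37, and it did not pass the limma test over all genes (adjusted p = 0.141). Without YOD1 library 2 the log2 fold change was 0.67 (adjusted p = 0.117 in limma). The sources used here do not say whether the introduced sequence is the mouse one, so these values may not count the transgene. The authors' deposited table lists Yod1 with q = 0.031 and marks it as significant. Jak2 (ENSMUSG00000024789) stood at 1.71 ± 0.63 FPKM in the controls and 1.14 ± 0.22 FPKM in the YOD1 libraries (SD, n = 3 each), with overlapping groups and a log2 fold change of -0.32 with an SE of 0.19 (limma adjusted p = 0.338). It lay between -0.48 and -0.15 when 1 library was left out and was -0.13 after length and GC correction. The authors' deposited table gives Jak2 q = 0.541. Transcript levels say nothing about the stability of the JAK2 protein.

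Over all genes, 55 of 11483 tested passed the limma test at an adjusted p of 0.05, and 51 of them were higher and 4 lower with YOD1 overexpression. At an unadjusted p under 0.05 the balance was the other way, with 904 higher and 1494 lower, and with median-ratio scaling it was 1356 and 869. Among the 51 were interferon-induced genes, chemokine and acute-phase genes, rRNA-derived transcripts and histone genes. Irf7, a transcription factor of the interferon response, rose from 3.26 ± 0.57 to 52.8 ± 35.5 FPKM (SD, n = 3 each), a log2 fold change of 3.47 with an SE of 0.37 (adjusted p = 0.00534 in limma). Ccl5, a chemokine that attracts T cells and monocytes, rose from 0.894 ± 0.422 to 12.6 ± 4.36 FPKM (log2 fold change 2.82, adjusted p = 0.00359 in limma). Ifitm3, a membrane protein that restricts virus entry, rose from 46.7 ± 5.68 to 241 ± 99.5 FPKM (log2 fold change 2.27, adjusted p = 0.00672 in limma). Saa3, an acute-phase serum amyloid gene, rose from 19.8 ± 2.63 to 87.0 ± 14.6 FPKM (log2 fold change 2.07, adjusted p = 0.00228 in limma). Apol9b, an apolipoprotein L gene with a near-identical neighbour, Apol9a, had a log2 fold change of 3.31, and its value is uncertain where reads of both copies were split.

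The ribosomal sequence Rn18s-rs5, related to 18S rRNA, rose from 1826 ± 514 to 10320 ± 2559 FPKM (SD, n = 3 each, log2 fold change 2.51, limma adjusted p = 0.00631). It made up 0.421% to 0.733% of the FPKM sum in the controls and 2.17% to 3.90% in the YOD1 libraries. The noncoding transcript AY036118 had a log2 fold change of 4.11, with means of 10.6 and 226 FPKM. The histone genes H4c12 and H4c2 and the histone pseudogene H2af-ps2 had log2 fold changes of 2.80, 2.35 and 2.50. Histone genes of 1 family are close in sequence, so their single values are uncertain. A count made after the values were seen found 28 replication-dependent histone symbols among the tested genes, of which 11 were called higher and 27 had a log2 fold change above 0.

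The 4 genes that passed the test in the lower direction were Gm49320, Cpt1a, Mettl7a1 and Srxn1. Cpt1a, the enzyme that commits long-chain fatty acids to mitochondrial oxidation, fell from 19.9 ± 2.05 to 9.37 ± 1.04 FPKM (SD, n = 3 each, log2 fold change -1.01, limma adjusted p = 0.0179). Srxn1, a sulfiredoxin that restores oxidised peroxiredoxins, fell from 20.05 ± 0.770 to 11.1 ± 1.19 FPKM (log2 fold change -0.81, limma adjusted p = 0.0355). Gm49320, a predicted gene, and Mettl7a1, a methyltransferase-like gene, had log2 fold changes of -1.94 and -0.86. The next genes by p-value did not pass: Prph, an intermediate filament gene (-1.13), Ralgds (-0.89), Tmem50b (-0.81), Dag1 (-0.66), the stearoyl-CoA desaturase gene Scd2 (-1.19) and Chdh (-0.90) had limma adjusted p from 0.0501 to 0.0627. All 55 called genes had no overlap between the groups, against 3315 of the 11483 tested genes (28.9%), where chance gives 10% for a gene taken alone. A gene that passes the test rarely has overlapping groups, and genes share trends across libraries. Neither share is therefore independent support.

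**Figure D1:**
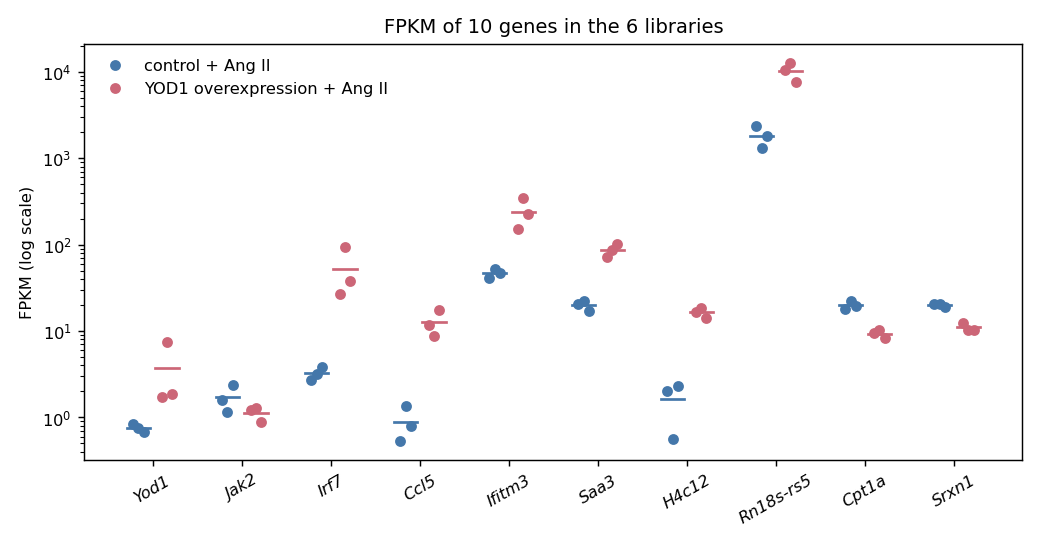
FPKM of 10 genes on a log axis, with a dot for each of the 3 control libraries (blue) and 3 YOD1 libraries (red) and a line at the group mean. Irf7, Ccl5, Ifitm3, Saa3, H4c12 and Rn18s-rs5 lay higher and Cpt1a and Srxn1 lower in all 3 YOD1 libraries, while the Jak2 values of the groups overlapped and Yod1 was highest in YOD1 library 2 (7.56 FPKM).

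The number of calls depended on single libraries. Without control 3 the test called 145 genes higher and 97 lower, and without YOD1 library 3 it called 107 and 25. Without control 1 it called 30 and 1, and without control 2 it called 17 and 2. Of the 55 genes, 18 to 52 were called again when a library was left out, and all 55 kept their sign. In all 6 such fits 17 genes were called, among them Irf7, Ccl5, Ifitm3, Saa3, Ifi27, Rn18s-rs5, H4c12, H4c2 and Gm49320. H4c1 was called in 1 of the 6, Srxn1 and Mettl7a1 in 2, Cpt1a and H2af-ps2 in 3, and H1f4, Bst2, Psmb8, Cebpd, Apol9b and AY036118 in 4. The higher calls lay mostly in short transcripts. Among 10 bins of transcript length with equal gene numbers, the shortest (up to 925 bp) held 19 genes called higher. The bins of 927 to 1520 bp and 1521 to 2039 bp held 7 each, and the longest held 0. Removing trends of transcript length and GC content, a setting chosen after seeing the data, left 14 genes higher and 6 lower, so that 70% of calls were higher in place of 92.7%. Of the 55 genes, 48 could be tested in that setting, 16 were called again and 48 kept their sign. The 32 no longer called, Ifitm3, Bst2, Psmb8, Apol9b, AY036118, H4c2, H1f4, H4c1, H2af-ps2 and Srxn1 among them, had adjusted p from 0.0518 to 0.111. They kept a median of 84% of their log2 fold change, while their median SE went from 0.208 to 0.231. The folds and SE of single genes went either way (Srxn1 from -0.81 to -0.84, SE from 0.132 to 0.124), and why these calls ended was not tested.

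Annotation terms were tested among the called genes against all 11483 tested genes with Fisher's exact test. Of 3249 terms, 17 were enriched among the 51 higher genes. The leading 14 rested mainly on histone genes, such as structural constituent of chromatin, with 11 called genes where 0.204 were expected (Fisher's exact test, adjusted p = 8.08e-14). Fisher's exact test takes genes as independent, while these histone genes are close in sequence and recur across the 14 terms. Their p-values and the number of terms therefore overstate the evidence. The other 3 were interferon and antiviral terms, each with 3 called genes, and Ifitm3 was in all 3. Type I interferon signaling held Ifi27, Ifitm3 and Irf7 (Fisher's exact test, adjusted p = 0.00901), and response to interferon-gamma held Bst2, Ccl5 and Ifitm3 (adjusted p = 0.00496). The 4 lower genes gave 0 enriched terms.

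Of 33 gene lists fixed before the data were examined, 31 had at least 5 tested members. With camera from limma at a preset correlation of 0.01, 8 lists were higher and 5 lower than other genes. With an estimated correlation none of these 13 calls held in camera, and 1 of the 31 lists, the histones, had an unadjusted p under 0.05 (p = 0.0291).

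Interferon-stimulated genes, which respond to interferon through JAK kinases and STAT transcription factors, were higher as a list. Of 29 tested members, 27 had a log2 fold change above 0, with a median of 1.21 (camera adjusted p = 4.44e-18, adjusted p = 0.517 with an estimated correlation). Over all genes 3 members passed the limma test, and 21 passed when adjusted over the list alone. Irf7, Ifi27 (log2 fold change 1.89) and Bst2, an antiviral tether (1.37), were those 3. Isg15, a ubiquitin-like modifier, stood at 6.77 and 56.1 FPKM, and Usp18, the protease that removes it, at 1.36 and 24.1 FPKM, without passing over all genes (limma adjusted p = 0.0501 and 0.0759). The median of the list was 0.77, 1.95 and 0.86 in YOD1 libraries 1, 2 and 3, and the median log2 fold change was 0.78 without YOD1 library 2. The rRNA share was also higher in all 3 YOD1 libraries.

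Genes of JAK-STAT signalling had smaller fold changes. Of 29 tested receptor, kinase, STAT and regulator genes, 23 had a log2 fold change below 0. The list median was -0.25, against -0.10 over all tested genes. Camera put the list lower (adjusted p = 0.045, adjusted p = 0.556 with an estimated correlation). No member passed over all genes by limma, 10 of 29 had groups that did not overlap (against 28.9% of all tested genes), and 1 passed when adjusted over the list alone, Pias3, an inhibitor of activated STAT3 (21.8 and 13.8 FPKM). Stat3 stood at 9.57 ± 0.72 and 7.02 ± 0.99 FPKM (SD, n = 3 each), lower in 3 of 3 libraries (log2 fold change -0.40, limma adjusted p = 0.189). The list was no longer called without YOD1 library 1 (adjusted p = 0.136 in camera), YOD1 library 3 (0.0658), control 1 (0.0592) or control 2 (0.11), or after length and GC correction (0.159). Its median was -0.38 without YOD1 library 2 and -0.125 without YOD1 library 3. After length and GC correction it was -0.156, against -0.089 over all genes in that setting.

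STAT3 targets were higher as a list while their members went both ways. Of 31 tested, 16 had a log2 fold change above 0, with a median of 0.04 (camera adjusted p = 0.0315, adjusted p = 0.517 with an estimated correlation). Saa3 and Cebpd, a transcription factor of the acute-phase response (0.880 and 4.52 FPKM, log2 fold change 1.53), passed over all genes. Adjusted over the list alone, 7 members were higher and 3 lower, Egr1 among the latter (51.4 and 11.97 FPKM). Socs3, a STAT3-induced inhibitor of JAK kinases, had a log2 fold change of -0.04 (limma adjusted p = 0.902). Without control 3 the list was not called (camera adjusted p = 0.211), nor without YOD1 library 2 (0.0681), and its median was then -0.092 and -0.072. Without YOD1 library 1 the median was 0.025.

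NF-kB and inflammatory cytokine genes had a median of 0.10 over 28 tested members (camera adjusted p = 0.0247, adjusted p = 0.517 with an estimated correlation). Ccl5 passed over all genes and 5 members passed when adjusted over the list alone, among them Nfkbia, the inhibitor of NF-kB (28.8 and 39.3 FPKM). Without control 3 the list was not called (camera adjusted p = 0.406). Its median was 0.043, -0.0024 and 0.063 without YOD1 libraries 1, 2 and 3, and 0.155, 0.025 and 0.013 without controls 1, 2 and 3. The list of senescence and secretory genes had a median of 0.14 over 13 tested members (camera adjusted p = 0.00887, adjusted p = 0.517 with an estimated correlation). None of its members passed over all genes and 4 passed when adjusted over the list alone, among them the cell cycle inhibitor Cdkn2a (57.9 and 141 FPKM) and the stress cytokine Gdf15 (69.5 and 128 FPKM). Its median was 0.081 without YOD1 library 1, 0.278 without control 1 and 0.062 without control 2. After length and GC correction the list was not called (camera adjusted p = 0.154).

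Replication-dependent histones, whose transcripts end in a stem-loop and not in a poly(A) tail, had a list median of 1.34 over 8 tested members, all above 0 (camera adjusted p = 1.01e-09, adjusted p = 0.517 with an estimated correlation). H4c2, H1f4 (1.37 and 5.46 FPKM) and H4c1 (0.348 and 2.40 FPKM) passed over all genes, and 6 passed when adjusted over the list alone. The DNA replication and G1-S list, with 30 tested members, had a median of 0.04 (camera adjusted p = 0.045, adjusted p = 0.53 with an estimated correlation), and 0 members passed over all genes by limma or when adjusted over the list alone. The latter call was lost without control 3 (camera adjusted p = 0.115), control 2 (0.11), YOD1 library 1 (0.0932) or YOD1 library 2 (0.0756), and the median lay between -0.011 and 0.121 when 1 library was left out. Mitosis and G2-M genes had a median of -0.34 over 29 tested members, 24 below 0 (camera adjusted p = 0.000809, adjusted p = 0.556 with an estimated correlation). Mki67, a proliferation marker, stood at 2.53 and 0.932 FPKM and the spindle checkpoint kinase Bub1 at 4.71 and 2.05 FPKM. None passed over all genes and 13 passed when adjusted over the list alone.

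Cytosolic ribosomal protein genes had a median of 0.31 over 36 tested members, 33 above 0 (camera adjusted p = 1.35e-09, adjusted p = 0.517 with an estimated correlation). None passed over all genes, and 2 passed when adjusted over the list alone, Rpl13 (87.9 and 261 FPKM) and Rps3 (336 and 544 FPKM). Nuclear genes of oxidative phosphorylation had a median of 0.15 over 31 tested members (camera adjusted p = 0.000386, adjusted p = 0.517 with an estimated correlation), and 1 passed when adjusted over the list alone, Cox5b (8.04 and 21.4 FPKM). The median of the latter list was 0.080 without YOD1 library 1, 0.078 without YOD1 library 3 and 0.088 without control 2. Both lists hold short transcripts, with median lengths of 1200 and 1661 bp against 3018 bp over the tested genes. Across genes, which are not independent replicates, fold change and transcript length had a Spearman correlation of -0.404. The median log2 fold change was 0.09 in the shortest of 10 length bins of equal gene number and -0.30 in the longest. The shortest bin exceeded the longest by 0.20, -0.10 and 0.53 in YOD1 libraries 1, 2 and 3 and by -0.11, -0.25 and -0.21 in the controls. The 13 mitochondrially encoded transcripts had a median of -0.05 and were not called (camera adjusted p = 0.884), but were called lower without YOD1 library 3 (0.0477).

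**Figure D2:**
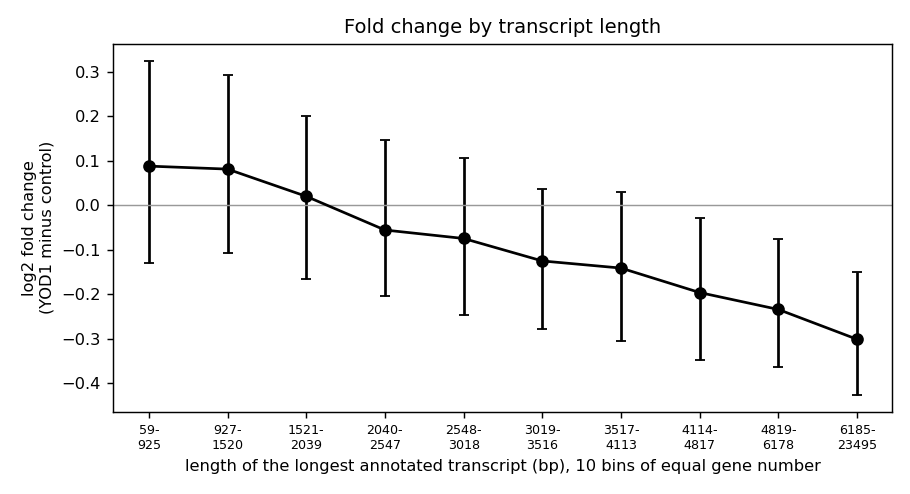
Median log2 fold change (YOD1 minus control) of the tested genes in 10 bins of transcript length in bp, with bars from the lower to the upper quartile. The median went from 0.09 in the shortest bin to -0.30 in the longest.

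Cholesterol synthesis genes, the targets of SREBP2, were lower together. All 24 tested members had a log2 fold change below 0, with a median of -0.98 (camera adjusted p = 1.35e-09, adjusted p = 0.517 with an estimated correlation). Hmgcs1 stood at 44.3 and 11.2 FPKM, the squalene epoxidase gene Sqle at 28.2 and 13.7 FPKM, and Idi1 at 16.6 and 4.12 FPKM. None passed over all genes by limma, and 19 passed when adjusted over the list alone. Control 3 lay near the YOD1 libraries, with a list median of -0.69 relative to the control mean, against 0.35 and 0.24 in controls 1 and 2 and -0.78, -1.02 and -0.99 in the YOD1 libraries. Immediate early genes showed the same split, with a median of -0.73 in control 3 and of -0.50, -0.51 and -0.55 in the YOD1 libraries. That list had a median log2 fold change of -0.51 over 21 tested members (camera adjusted p = 0.0192, adjusted p = 0.721 with an estimated correlation), with 0 members past the limma test over all genes and 1 lower and 1 higher when adjusted over the list alone, Egr1 and Junb (23.2 and 46.3 FPKM). It was not called without control 1 (camera adjusted p = 0.267) or control 2 (0.114), and its median was -0.83 without control 3.

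NRF2 targets, the antioxidant response genes, had a median of -0.34 over 19 tested members, 16 below 0 (camera adjusted p = 0.00887, adjusted p = 0.517 with an estimated correlation). Srxn1 passed over all genes and 5 passed when adjusted over the list alone, among them Gclm, of glutathione synthesis (12.5 and 6.70 FPKM), and the quinone reductase Nqo1 (15.2 and 6.98 FPKM). The call was lost without control 3 (camera adjusted p = 0.0962) or YOD1 library 2 (0.0575). Fatty acid oxidation genes were not called as a list (median -0.22 over 18 tested, camera adjusted p = 0.3). Adjusted over that list alone 3 members were lower, among them Cpt1a and Etfdh (4.48 and 2.52 FPKM).

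Lists tied to fibrosis were not called. Collagens and extracellular matrix had a median of -0.08 over 27 tested members (camera adjusted p = 0.892), matrix remodelling and crosslinking -0.06 over 26 (0.918), TGF-beta signalling and targets -0.09 over 22 (0.688) and YAP-TEAD targets -0.06 over 21 (0.362). The list of epithelial-mesenchymal transition had a median of -0.05 over 23 tested members (0.116) and was called higher without control 3 (camera adjusted p = 0.0332). When 1 library was left out these medians lay between -0.17 and 0.04 for collagens, -0.09 and -0.01 for matrix remodelling, -0.13 and -0.03 for TGF-beta, -0.19 and 0.18 for YAP-TEAD targets and -0.05 and 0.09 for the transition. Adjusted over their lists alone, Timp2 was lower among the matrix remodelling genes, Krt7 higher among the transition genes, and Ccn2 and Id1 higher among the TGF-beta genes, with 0 passing in the collagen and YAP-TEAD lists. Of single genes, Acta2 (log2 fold change 0.41), Fn1 (-0.11), Col1a1 (-0.34), Vim (0.29), Cdh1 (-0.18) and Tgfb1 (-0.08) did not pass and had overlapping groups (limma adjusted p from 0.296 to 0.781). Without 1 library Acta2 lay between 0.22 and 0.64, Fn1 between -0.28 and 0.08, Col1a1 between -0.522 and 0.00276, Vim between 0.19 and 0.47, Cdh1 between -0.26 and -0.02 and Tgfb1 between -0.20 and 0.02. Ccn2, a profibrotic matricellular gene, stood at 10.9 ± 1.40 and 16.3 ± 0.351 FPKM (SD, n = 3 each), higher in 3 of 3 libraries and not past the test (log2 fold change 0.54, limma adjusted p = 0.111).

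Tubular injury markers were not called (median -0.10 over 16 tested, camera adjusted p = 0.75), nor were tubular transporters and identity genes (median -0.22 over 12 tested, camera adjusted p = 0.362). Adjusted over their lists alone, Krt7 and Lcn2 were higher and Timp2 lower among the injury markers, and the transcription factor gene Pax8 and the kidney cadherin gene Cdh16 were lower among the identity genes. The injury marker Lcn2 stood at 75.6 ± 4.79 and 102 ± 10.9 FPKM (log2 fold change 0.42, limma adjusted p = 0.133). Havcr1, which encodes KIM-1, stood at 0.351 and 0.950 FPKM and the Ang II receptor gene Agtr1a at 0.055 and 0.026 FPKM, both below the filter and untested. The renin-angiotensin list had 3 members above the filter and was not tested as a list. Its members Lnpep, Agtrap and Atp6ap2 had log2 fold changes of -0.39, -0.28 and -0.42.

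The list of OTU deubiquitinases and YOD1 partners had a median of -0.23 over 23 tested members (camera adjusted p = 0.263). Vcp, the segregase with which YOD1 works, stood at 45.5 and 31.1 FPKM without passing (limma adjusted p = 0.14). The unfolded protein response and ERAD list was not called (median -0.02 over 36 tested, camera adjusted p = 0.391), nor were heat shock and proteasome genes (median -0.00088 over 31 tested, camera adjusted p = 0.0671). In the latter, the immunoproteasome gene Psmb8 rose from 7.35 ± 1.69 to 21.8 ± 4.47 FPKM (SD, n = 3 each, log2 fold change 1.45, limma adjusted p = 0.0142), while the chaperone gene Hspa8 stood at 256 and 139 FPKM. Adjusted over the list alone, 4 members were higher and 2 lower. The lists of p53 targets (median -0.08, camera adjusted p = 0.467), apoptosis and autophagy (-0.22, 0.121) and hypoxia and glycolysis (0.05, 0.331) were not called, and 1 gene passed when adjusted over its list alone, the p53 target Aen. Without control 3 the apoptosis list was called lower (camera adjusted p = 0.0481).

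Among markers of other cell types, leukocyte genes had a median of 0.29 over 6 tested members (camera adjusted p = 0.0671), and the list was called higher without YOD1 library 1 (camera adjusted p = 0.00957) or control 2 (0.0379). Lyz2, the lysozyme of myeloid cells, stood at 6.22 and 15.7 FPKM and the pan-leukocyte gene Ptprc at 0.027 and 0.056 FPKM. Fibroblast and pericyte genes (median -0.09 over 6 tested, camera adjusted p = 0.884) and podocyte genes (0.05 over 5 tested, 0.467) were not called. The endothelial list had 3 tested members, Plvap, Eng and Cldn5, with log2 fold changes of 0.51, 0.44 and 0.27, and was not tested as a list. Adjusted over the list alone Plvap and Eng were higher (both 0.0394), in 3 of 3 libraries each, while none passed over all genes. Of the lists not called, medians without 1 library also crossed 0 for unfolded protein response (-0.115 to 0.067), heat shock (-0.086 to 0.118), hypoxia (-0.029 to 0.052), mitochondrial (-0.239 to 0.124), fibroblast (-0.253 to 0.029) and podocyte genes (-0.028 to 0.117). Those of p53 targets (-0.102 to -0.020), OTU deubiquitinases (-0.281 to -0.148), injury markers (-0.141 to -0.039), fatty acid oxidation (-0.287 to -0.096), apoptosis (-0.256 to -0.145), tubular identity (-0.260 to -0.153) and leukocyte genes (0.205 to 0.436) kept their sign. For the transition, TGF-beta, YAP-TEAD, unfolded protein, heat shock, p53, injury, mitochondrial and fibroblast lists the median lay below 0 while camera, which compares a list with other genes (median -0.10), gave the higher direction.

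**Figure D3:**
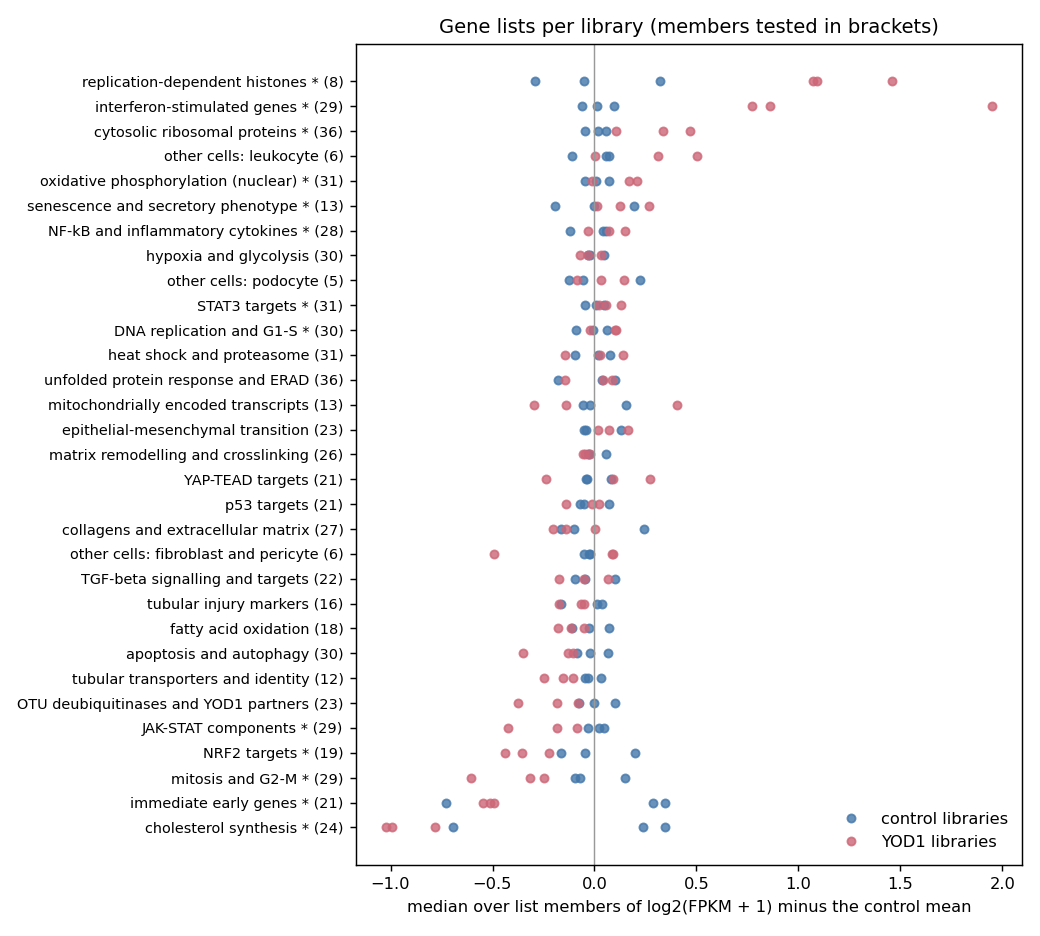
Median over the tested members of each gene list of log2(FPKM + 1) minus the control mean, with a blue dot for each control and a red dot for each YOD1 library. A star marks lists called by camera at the preset correlation, and in cholesterol synthesis and immediate early genes control 3 (-0.69 and -0.73) lay with the YOD1 libraries.

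The authors' deposited table marks 286 genes as significant, 190 higher and 96 lower, all with q under 0.05 and an absolute log2 fold change of at least 1. Of these, 201 were tested here and 85 lay below the filter. The limma test called 47 of the 201, where 0.963 shared calls are expected if both selections were independent, which they are not since both come from the same values. The other 154 had the same sign and an unadjusted p under 0.05 in limma. Of the genes marked in the authors' deposited table, 8 have a value above 0 in only 1 library, and 17 have overlapping groups.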

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

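The count of genes higher (51) and lower (4) was 0 and 0 in limma with no filter (1411 and 2016 at an unadjusted p under 0.05), 160 and 9 with median-ratio scaling, and 28 higher with rRNA left out and a common total, which changed 2 choices at once. It was 14 higher after length and GC correction and 2 lower with a log2 fold change of at least 1. Leaving out 1 library gave 17 to 145 higher and 1 to 97 lower. The causes were not tested. The replicate block gave 33 higher and 8 lower and called 32 of the 55 genes again. Deviations of same-numbered libraries correlated across genes with r of 0.296, -0.121 and -0.112. For pairs with different numbers r lay between -0.409 and 0.339. These values gave no sign that the numbers pair the samples, but so few libraries cannot exclude it. The block also called the leukocyte list (adjusted p = 0.044). All 55 genes kept their sign in every setting that tested them, and neither Yod1 nor Jak2 changed direction or passed.

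The number of lists higher (8) and lower (5) was 4 and 3 with the stricter filter, where 27 lists were tested and the histones were not, 0 and 0 with an estimated correlation (1 and 0 at an unadjusted p under 0.05), and 0 and 1 with fry (2 and 5 unadjusted). It was 3 to 5 lower without 1 library. With an estimated correlation the adjusted p of camera was 0.517 for interferon-stimulated, STAT3, NF-kB, senescence, oxidative phosphorylation, cholesterol, NRF2, ribosomal and histone lists, 0.53 for DNA replication, 0.556 for JAK-STAT and mitosis and 0.721 for immediate early genes. With fry it was 0.177 for JAK-STAT, STAT3, interferon-stimulated, cholesterol and ribosomal lists, 0.31 for NF-kB, 0.219 for mitosis and senescence, 0.636 for DNA replication, 0.228 for oxidative phosphorylation, 0.152 for NRF2, 0.494 for immediate early genes, 0.0912 for histones and 0.0398 for tubular transporters, the list that passed.

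Other calls were lost with the stricter filter for STAT3 and immediate early genes (both 0.115), mitosis (0.0573), DNA replication (0.101) and senescence (0.0541), with median-ratio scaling for JAK-STAT (0.0607) and STAT3 (0.0598), with length and GC correction for JAK-STAT and STAT3 (both 0.159) and senescence (0.154), and with rRNA left out and a common total for DNA replication (0.0694). Leaving out 1 library gave adjusted p of 0.0212 to 0.136 for JAK-STAT, 0.00911 to 0.211 for STAT3, 0.00322 to 0.406 for NF-kB, 0.0146 to 0.115 for DNA replication, 0.000275 to 0.0962 for NRF2 and 5.18e-11 to 0.267 for immediate early genes. For lists not called it gave 0.0332 to 0.265 for epithelial-mesenchymal transition, 0.0481 to 0.265 for apoptosis and 0.00957 to 0.239 for leukocytes.

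Some lists not called changed direction, and only mitochondrial transcripts were then called (lower without YOD1 library 3). Leaving out 1 library did so within adjusted p of 0.251 to 0.707 for collagens, 0.651 to 0.973 for matrix remodelling, 0.0768 to 0.924 for the unfolded protein response, 0.265 to 0.996 for p53, 0.0477 to 0.984 for mitochondrial transcripts and 0.464 to 0.975 for fibroblasts. Length and GC correction turned collagens (0.161), matrix remodelling (0.666), injury markers (0.673) and mitochondrial transcripts (0.392). Median-ratio scaling turned matrix remodelling (0.891), and mitochondrial transcripts turned with the stricter filter (0.923) and with rRNA left out and a common total (0.949). Fry gave the other direction for TGF-beta (0.871), unfolded protein response (0.957), p53 (0.96), injury markers (0.847), mitochondrial transcripts (0.92) and fibroblasts (0.775). Of named genes, Socs3 turned with median-ratio scaling (log2 fold change 0.0586) and lay between -0.147 and 0.0504 without 1 library, and Tgfb1 turned likewise (0.0195, and -0.201 to 0.0246). Fn1 turned after length and GC correction (0.0672) and lay between -0.276 and 0.0793, and Col1a1 between -0.522 and 0.00276. The cause of these changes was not tested.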

Other observations

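The gene groups and the tests on patterns in this part were chosen after the values were seen, except for the counts over other splits of the libraries. The p-values of these groups are therefore no independent support. Genes of class I antigen presentation had 16 of 20 tested members above 0 and a median log2 fold change of 0.52 (camera adjusted p = 8.58e-11 over the 5 groups chosen here, adjusted p = 0.0982 with an estimated correlation). Psmb8 and H2-T23 passed the limma test over all genes. H2-D1 and H2-K1, the classical class I heavy chains, ranged from 234 to 287 FPKM and from 247 to 283 FPKM in the controls, against 385 to 604 FPKM and 388 to 545 FPKM in the YOD1 libraries. Both did not pass (limma adjusted p = 0.0768 and 0.0805), nor did B2m (log2 fold change 0.28, limma adjusted p = 0.361). The 4 members below 0 were H2-T24, Tapbpl, Pdia3 and Tap2. Values of H2 genes are uncertain because the copies are close in sequence. Acute-phase and complement genes had a median of 0.62 over 13 tested members, 12 above 0 (camera adjusted p = 6.77e-10, adjusted p = 0.0982 with an estimated correlation). The complement factor gene Cfb stood at 2.24 to 3.01 FPKM in the controls and 9.07 to 16.3 FPKM in the YOD1 libraries.

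Genes of fatty acid synthesis and desaturation lay below 0 in 16 of 16 tested members, with a median of -0.54 (camera adjusted p = 4.33e-07, adjusted p = 0.119 with an estimated correlation). None passed the limma test over all genes, and 10 passed when adjusted over the list alone. Fasn, the fatty acid synthase, stood at 275, 387 and 96.8 FPKM in controls 1, 2 and 3 and at 56.7 to 77.7 FPKM in the YOD1 libraries, so control 3 lay nearer to the YOD1 libraries, as it did for cholesterol synthesis. Scd1 stood at 83.4 to 118 FPKM and 42.2 to 65.0 FPKM.

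The rise of rRNA-derived and replication-dependent histone transcripts is the first pattern weighed, since neither kind carries a poly(A) tail. Histone genes with polyadenylated transcripts had a median of -0.01 over 9 members, so the change was not shared by histone genes at large. The DNA replication and G1-S list had a median of 0.0369 against 1.34 for the histones. By the bound set this spoke against a larger share of cells in S phase. That bound took both lists to move about as much, which was not tested. Camera also put the DNA replication list above other genes (adjusted p = 0.045, and 0.53 with an estimated correlation), so this test cannot decide. After correction for transcript length and GC the histone median was 1.15, which argues against these trends, as modelled, as the whole cause. The correction took the longest annotated transcript of each gene, and the list members are not independent. Less complete poly(A) selection in the YOD1 libraries cannot be told apart from a change in the cells: 6 other RNAs without poly(A) tails had a median of 0.817, but 5 of the 6 overlapped between groups because control 1 was high (Rn7sk 29.0 FPKM against 25.5 to 30.5 FPKM in the YOD1 libraries). Among the 6, Rn7s1 and Rn7s2 had near-identical values (129 and 133 FPKM in control 1), so the 6 are not independent. Outside the 6, the small nucleolar RNA Snord55 (log2 fold change 1.14) and 5 unnamed genes of miRNA biotype were also called higher. An effect of YOD1 itself on the rRNA-derived and histone transcripts was not tested.

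The lists of ribosomal proteins and oxidative phosphorylation hold short transcripts, and short transcripts were higher relative to long ones in YOD1 libraries 1 and 3 (shortest minus longest bin 0.20 and 0.53), while YOD1 library 2 (-0.10) lay near control 1 (-0.11). After correction for length and GC the ribosomal list stayed 0.291 above the median of all genes (0.414 before, with SE of 0.051 and 0.046 over its members, camera adjusted p = 1.69e-05). By the bound set this spoke against these trends as its whole cause. The correction took the longest annotated transcript of each gene, and members of a list are not independent, so the test cannot decide. The list median was 0.334, 0.108 and 0.467 in YOD1 libraries 1, 2 and 3 and 0.055, -0.049 and 0.015 in the controls. Across the 6 libraries it ranked in the same order as the shortest minus longest bin. The oxidative phosphorylation list came to 0.0693 above all genes, 27.8% of its size before, although camera still called it (adjusted p = 0.0399), so length and GC may account for most of it. The bound that decided these readings was reworded after the values were seen, and the earlier wording, also set after they were seen, gave the same readings. What lies behind the length trend was not tested.

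The higher interferon-stimulated genes are the third pattern. Length and GC as the whole cause are argued against, since the list lay 1.26 above all genes after correction, 96.5% of its size before. Leukocytes among the cells were left undecided by 2 tests. In the first, 5 leukocyte genes were higher in sum by 10.6 FPKM, 2.31% of the 458 FPKM summed difference of the list and between the bounds that would decide it. In the second, added after the first was read, their median difference was 0.302 FPKM against 4.40 FPKM for the list, and 3 of the 5 lay under 10% of the latter where 4 were asked for. Most of the sum was Lyz2, a gene of myeloid cells (6.22 and 15.7 FPKM). Ptprc at 0.027 and 0.056 FPKM speaks against a large share of leukocytes, but it is a single gene near the floor. Laptm5, Tyrobp and Fcer1g were also low, with means of 0.455, 0.785 and 1.09 FPKM in the YOD1 libraries. The means of all 5 genes were higher in the YOD1 libraries, but only Laptm5 and Lyz2 had groups that did not overlap. The labels name a single cell line and give no leukocyte source. A response to YOD1 and a response to the way it was delivered could both give this pattern and are confounded by the design, since the sources used here do not describe the vector of the controls.

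The count of 51 genes higher was reached by 1 of the 10 splits of the 6 libraries, the real one, and the highest other split gave 1. The 4 genes lower likewise came from 1 of 10 splits, with 1 as the highest other. The 13 lists called at the preset correlation were also the largest count, in 1 of 10 splits, but another split gave 12, the split that sets YOD1 library 1 with controls 2 and 3 against the rest. Splits of 3 against 3 are too few for a share under 0.05. Camera with a preset correlation thus called nearly as many lists for a division of the samples that follows the groups only in part. Each other split keeps part of the group difference between its arms and puts the rest within them. Its list calls are therefore not calls without a group signal, and the added spread lowers its gene counts.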
